A study of Mus musculus with 6 samples.

How the data were processed

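The series holds 6 RNA sequencing libraries of cultured mouse ovary, 3 from medium alone and 3 from medium with 2% PRP for 2 h. Per the labels' protocols, ovaries came from newborn mice 3 days after birth, RNA was purified with a column kit, and libraries were built with a SMARTER mRNA kit. The series text describes the PRP as human and activated with thrombin, whereas the sample labels say PRP. The labels do not say whether replicates are separate cultures, litters or animals, so p-values measure the spread between these samples, which may be technical. Groups and replicate numbers were taken from the sample titles.

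The authors deposited 1 table of raw counts per gene symbol, with Entrez identifiers and pathway annotation, for 27098 genes (18685 coding and 8413 non-coding). Per the submitters' processing notes, the build was GRCm38/mm10. The aligner, the counting tool, its strand setting and its annotation are not given in the sources used here. Reads shared between near-identical copies, overlapping genes or antisense partners can therefore have been assigned to either gene, which makes Eno1, ATP6, haemoglobin genes, ribosomal protein genes, Oip5os1 and D830031N03Rik uncertain. The spans of Slc30a1, Txnrd1, Bhlhe40, Bfsp1, Il11ra1, Pbrm1, Rbm15, Tcf21, Stat2, Gdf9, Foxo3 and Akt1 also overlap another gene of the table. Each column was matched to a sample by its title. The column for PRP 3 has its letters in another order than the sample's title, and it was taken as PRP 3 because every other title has a column of its own. Gene coordinates came from a RefSeq table of GRCm38 by Entrez identifier (26150 genes matched), and transcript GC content and length from GENCODE transcripts of the same build (18598 genes matched).

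Totals were 35568000 to 36568367 counts per library. Pairs of libraries differed beyond counting noise, with a Poisson chi-square per degree of freedom of 8.91 to 32.0, so that none was a duplicate.

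Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood F test, 17475 genes), PRP minus control, two-sided, with Benjamini-Hochberg adjustment at 0.05. Standard errors were derived from the log2 fold change and its F statistic, and intervals are at 95%. CPM values use TMM library sizes. Gene lists were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 33 lists. Each was tested again with an estimated correlation and with fry, and none of the 33 passed either. Of 567 list members, 552 were matched by symbol, 13 by Entrez identifier and 2 not at all. DESeq2 1.42.0, limma-voom, other scaling factors and filters, and leaving out each library were alternatives. The test, the groups, the lists, the rule for named genes and these alternatives were fixed before the data were examined. These 33 lists were drawn from general knowledge, and none was chosen on these samples.

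The named genes were, by that rule, up to 10 passing genes in each direction with non-overlapping groups, or the 5 with the smallest p-values where none passed. The rule also took the 4 members with the smallest p-values of each list past its threshold without the block, and a fixed set of genes with Fos, Egr1, Foxo3, Akt1, Kit, Kitl, Foxl2, Amh, Gdf9 and Ddx4, of which some results are not reported here. Each list's members were also adjusted over the list alone.

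Both groups carry the numbers 1 to 3. Deviations from the group means correlated at 0.24, 0.40 and 0.33 between libraries of the same number and at -0.02 or below between all others. Centring on group means pushes the other values below 0 where same-number values are positive, so they add no separate support. The numbers were therefore taken to pair the libraries, from the data and not from any label, and the fit with the replicate number as a block is printed beside the unpaired one where it changes a call. The first principal component of log2 CPM held 43.2% of the variance, of which 94.6% followed the replicate number (chance 40%), and the third held 11.3%, of which 86.4% followed the treatment (chance 20%, and chosen among 3 components). Alternatives to the blocked results, the correction for GC content and length (natural splines on log2 CPM per library), the pathway sets and 2 further lists were chosen after seeing the data.

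The procedure was tested on simulated data for PRP against control with 17475 genes, of which 50 were changed at each of 4 fold sizes. The changed genes were drawn from those with a mean log2 CPM above 3, so recovery among genes of fewer counts was not simulated. The unpaired fit recovered 6% of genes changed 1.25-fold, 48% at 1.5-fold, 90% at 2-fold and 96% at 3-fold, with 0 false calls among 120. The blocked fit recovered 54%, 94%, 100% and 100%, with 21 false calls among 195. In 20 simulations without any change, the blocked fit made at least 1 call in 20 of 20 draws under gene-wise dispersions and in 0 of 20 under dispersions on the trend, against 1 and 0 draws for the unpaired fit. All 5 of 5 lists shifted by 0.5 on the log2 scale were recovered in both fits, with 0 false calls among the other lists. Their members were drawn at random with independent noise, so false calls from correlated members could not show. Estimated correlations were 0.77 for stromal fibroblast, 0.67 for interferon-stimulated, 0.28 for hypoxia and -0.03 for ovarian surface epithelium genes. Smaller shifts, such as those of the reported lists other than the interferon-stimulated and erythroid lists, were not simulated.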

Results

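Messenger RNA was sequenced from ovaries of 3-day-old mice kept in DMEM/F12 medium for 2 h, either alone or with 2% platelet-rich plasma (PRP), a blood plasma fraction enriched in platelets and their growth factors. The ovary at this age holds mostly primordial follicles, each a dormant oocyte within a single layer of flat pregranulosa cells. The series text describes the PRP as human and activated with thrombin, and the labels name no control with thrombin or other plasma. There were 3 control libraries and 3 PRP libraries, numbered 1 to 3 in each group. Library totals ran from 35568000 to 35825931 counts in control and from 36037111 to 36568367 counts in PRP. Mitochondrially encoded genes took 1.87% ± 0.05 of the counts in control and 1.87% ± 0.16 in PRP (SD, n = 3). Haemoglobin genes took 0.122% of the counts in control 3 and between 0.0106% and 0.0222% in the other libraries. The replicate number accounted for 67.2% of the variance of log2 expression over 11203 genes, where chance gives 40%, and no other of the 15 ways to pair the libraries took more than 53.4%. The treatment accounted for 13.8%, where chance gives 20%, and 7 of the 10 splits into 3 and 3 libraries, the real one included, took as much. Of the variance left within pairs the treatment took 42%, where chance gives 33.3%.

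PRP was set against medium alone to ask which ovarian transcripts respond within 2 h and whether genes of the PI3K/Akt pathway, which governs the exit of primordial follicles from dormancy, are among them. The planned fit, which compared the libraries as 2 unpaired groups, called no gene of any kind. No label pairs the libraries, and their replicate numbers were taken as pairs from these same expression values. Within these pairs, the transcription factor genes Nr4a1, Egr1 and Junb rose by 0.38 ± 0.06, 0.26 ± 0.04 and 0.29 ± 0.05 on the log2 scale (SE, n = 3 per group). The zona pellucida genes Zp2 and Zp3 rose by 0.23 ± 0.04 and 0.24 ± 0.04. Slc30a1, a zinc exporter, fell by 0.39 ± 0.06, and Pdk4, a kinase that restrains pyruvate oxidation, fell by 0.41 ± 0.07. These calls are fragile: none passed in limma-voom with the block or without robust estimation, Junb and Zp3 did not pass after correction for GC content and length, and the blocked fit made calls in 20 of 20 simulations without any change under gene-wise dispersions. Among the gene groups, stromal fibroblast, ovarian surface epithelium and hypoxia genes lay higher in PRP and interferon-stimulated genes lay lower. None of these 4 list differences passed with an estimated correlation (adjusted p = 0.966 without and 0.801 with the block), and the interferon list did not pass without control 3 (adjusted p = 0.365). Without the block, 7 of the 10 splits into 3 and 3 libraries gave at least 4 passing lists, the real split included. The highest other split gave 16. No gene of the fixed PI3K-AKT-mTOR list passed in either fit.

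Without pairing, 0 of 17475 genes passed an adjusted p of 0.05 in edgeR, and 557 had an unadjusted p under 0.05 where chance gives 874. DESeq2 and limma-voom also called 0 genes, with 551 and 564 at that unadjusted level. In 9.21% of the genes the 3 libraries of a group all lay on one side of the other group's, where chance gives 10%. With the replicate number as a block, 21 genes passed, 14 higher and 7 lower, and 1960 had an unadjusted p under 0.05. Simulations without any change, in which genes varied independently, gave medians of 829.5 such genes under gene-wise dispersions and 844 under dispersions on the trend. The biological coefficient of variation was 18.3% without the block and 9.6% with it.

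**Figure D1:**
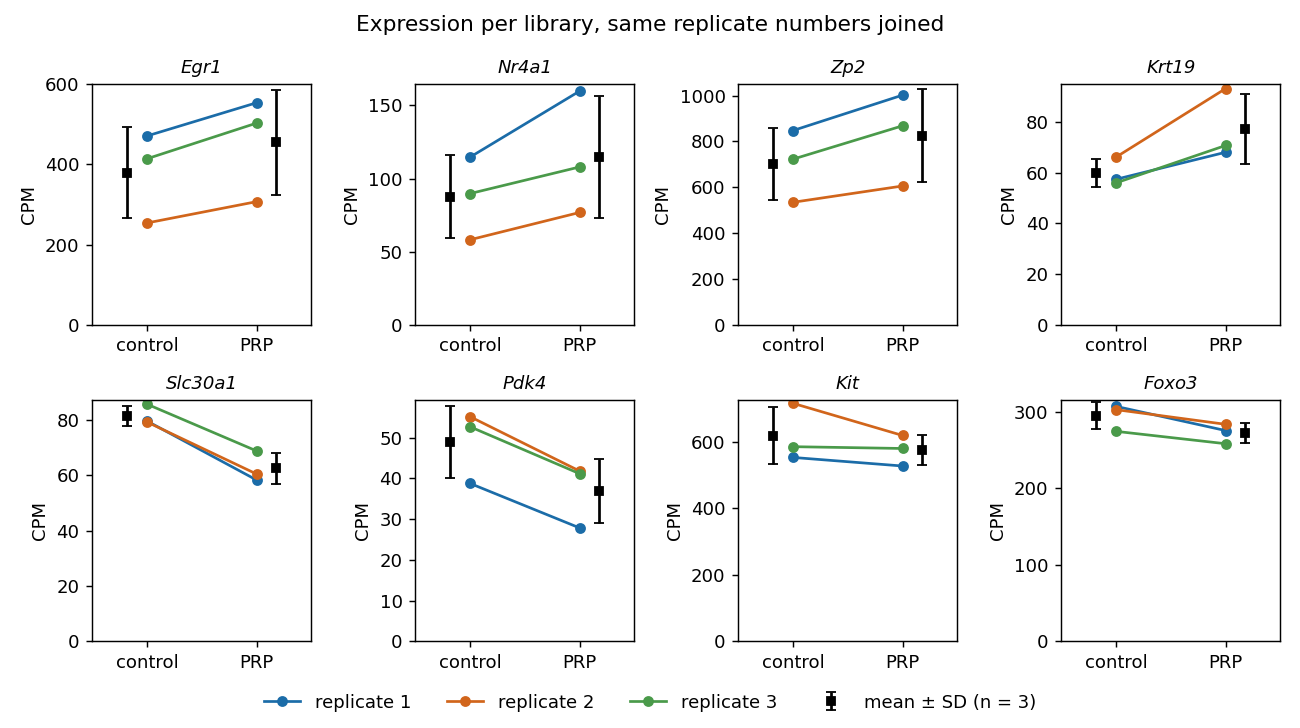
Expression of 8 genes in CPM (counts scaled to TMM library sizes) in each control and PRP library. Libraries of the same replicate number are joined, and black squares give the group mean ± SD (n = 3). Egr1, Nr4a1, Zp2 and Krt19 lay higher and Slc30a1, Pdk4, Kit and Foxo3 lay lower in PRP in all 3 pairs, although the groups overlapped for Egr1, Nr4a1, Zp2, Pdk4, Kit and Foxo3.

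Immediate early genes, whose transcripts are induced quickly by growth factors, were represented by 30 tested members. With the block, 4 of them rose over all genes tested, namely Nr4a1, Egr1, Zfp36 and Junb, and 8 rose and 1 fell adjusted over the list alone. After correction for GC content and length Nr4a1, Egr1 and Zfp36 passed (adjusted p = 0.0204, 0.0272 and 0.0388) and Junb did not (adjusted p = 0.13), and in limma-voom with the block none of the 4 passed. Egr1 (Entrez 13653, chromosome 18, 34861207 to 34864956) averaged 379.7 ± 112.5 CPM in control and 454.7 ± 130.3 CPM in PRP (SD, n = 3), with a blocked adjusted p of 0.0279. Nr4a1 (Entrez 15370, chromosome 15, 101253902 to 101274795) averaged 87.5 ± 28.3 CPM in control and 114.8 ± 42.0 CPM in PRP (SD, n = 3), with a blocked adjusted p of 0.0164. Zfp36, a factor that destabilises AU-rich transcripts, rose by 0.32 ± 0.05 (SE). Fos, the usual marker of this group, had a log2 fold change of 0.15 ± 0.33 without and 0.14 ± 0.09 with the block (SE), neither of which passed, and Egr3 was the member that fell, by 0.31 (adjusted over the list alone; chosen after its value was seen). Without the block 0 of the 30 members passed on either count. As a whole the list rose with the block (median log2 fold change 0.14, camera adjusted p = 0.0197, and 0.801 with an estimated correlation), and did not pass without it (adjusted p = 0.147). Its pair medians were uneven, at 0.023, 0.217 and 0.128. The blocked adjusted p was 0.0523 after correction for GC content and length, 0.127 without replicate 2 and 0.102 without replicate 3.

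Oocyte genes had a median log2 fold change of 0.09. Of 22 members tested, 16 had a log2 fold change above 0, 2 rose with the block over all genes tested, and 6 rose adjusted over the list alone. Zp2 (Entrez 22787, chromosome 7, 120126762 to 120145291) averaged 701.3 ± 157.6 CPM in control and 825.3 ± 202.0 CPM in PRP (SD, n = 3), and Zp3 (Entrez 22788, chromosome 5, 135980105 to 135988624) averaged 327.0 ± 103.8 and 390.3 ± 138.2 CPM. Their blocked adjusted p-values were 0.0331 and 0.0411, and after correction for GC content and length Zp2 passed (adjusted p = 0.0204) and Zp3 did not (adjusted p = 0.0923). Gdf9, an oocyte growth factor, had a log2 fold change of 0.10 (95% interval -0.22 to 0.43), and Ddx4, a germ cell RNA helicase, one of 0.03 (-0.12 to 0.19). In the unpaired fit 0 of the 22 members passed on either count. The list rose with the block (median 0.09, camera adjusted p = 0.0247; adjusted p = 0.801 with an estimated correlation), not without it (adjusted p = 0.424) and not in the blocked fit without replicate 3 (adjusted p = 0.364).

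Stromal fibroblast genes lay higher in PRP in 12 of 13 members, with a median log2 fold change of 0.16 and pair medians of 0.24, 0.17 and 0.12. The list rose in camera without the block (adjusted p = 0.00338) and with it (adjusted p = 0.000127). With an estimated correlation the adjusted p was 0.966 and 0.801, respectively. Without the block 0 of the 13 members passed on either count, and with it 11 rose adjusted over the list alone and 0 over all genes. Dpt and Lum, which organise collagen fibrils, had log2 fold changes of 0.61 ± 0.21 and 0.22 ± 0.10 (SE), Postn, a matricellular protein, 0.34 ± 0.16, and Tcf21, a mesenchymal transcription factor, 0.36 ± 0.15. Without the block the call was lost without control 2 (adjusted p = 0.244), without PRP 1 (0.0729) or without PRP 3 (0.114).

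Ovarian surface epithelium genes lay higher in 10 of 11 members, with a median of 0.16 and pair medians of 0.038, 0.055 and 0.284. The list rose without the block (camera adjusted p = 0.0389) and with it (adjusted p = 0.0247). With an estimated correlation the adjusted p was 0.966 and 0.801. Krt19, a simple-epithelial keratin, averaged 59.9 ± 5.5 CPM in control and 77.4 ± 13.8 CPM in PRP (SD, n = 3) and was the only member of the list to rise with the block (0.36 ± 0.06 SE, adjusted p = 0.0331), over all genes and adjusted over the list alone; it did not pass after correction for GC content and length (0.31 ± 0.06 SE, adjusted p = 0.0857). In the unpaired fit 0 of the 11 members passed on either count. Muc16, Upk3b and Krt7, the other members named, had log2 fold changes of 0.20 ± 0.10, 0.15 ± 0.10 and 0.19 ± 0.16 (SE). The unblocked call was lost without control 1, 2 or 3 (adjusted p = 0.155, 0.0555 and 0.0944) or PRP 3 (0.268), and the blocked call without replicate 3 (0.402).

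Hypoxia genes, targets of the oxygen-sensing HIF factors and enzymes of glycolysis, lay higher in 17 of 18 members with a median of 0.07. The list rose without the block (camera adjusted p = 0.00338) and with it (adjusted p = 0.00319), and the adjusted p with an estimated correlation was 0.966 and 0.801. Without the block 0 of the 18 members passed on either count, and 6 rose with the block adjusted over the list alone. Car9, a carbonic anhydrase, had a log2 fold change of 0.48 ± 0.16, Egln3, a prolyl hydroxylase, 0.30 ± 0.11, Ankrd37 0.54 ± 0.21 and the glycolytic enzyme Eno1 0.16 ± 0.07 (SE). Eno1 is uncertain because its near-identical copy Eno1b is counted beside it, and Car9 and Ankrd37 overlap neighbouring genes. The unblocked call was lost without control 2 (adjusted p = 0.186) or PRP 3 (0.114), and the blocked call without replicate 2 (0.095).

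Interferon-stimulated genes, the antiviral response group, lay lower in PRP in 14 of 15 members, with a median log2 fold change of -0.67. The list fell without the block (camera adjusted p = 0.000813) and with it (adjusted p = 0.000127), and the adjusted p with an estimated correlation was 0.966 and 0.801. Without the block 0 of the 15 members passed on either count. With it 2 members fell adjusted over the list alone, among them Stat2, a signal transducer of the interferon receptors, which fell by 0.35. Usp18, Rsad2 and Irf7 had log2 fold changes of -1.76 ± 0.79, -2.11 ± 0.98 and -0.77 ± 0.39 (SE). Control 3 held the highest value of the 6 libraries in 15 of 15 members, and its median excess over controls 1 and 2 was 2.7-fold. Erythroid genes were 15.5-fold and NF-kB targets 1.51-fold higher in the same library, against 1.19-fold for macrophage and leukocyte genes. The adjusted p of the interferon list was 0.365 without control 3, and 0.0919 with the block without replicate 3. Median pair differences of the list were -0.26, -0.10 and -1.29.

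**Figure D2:**
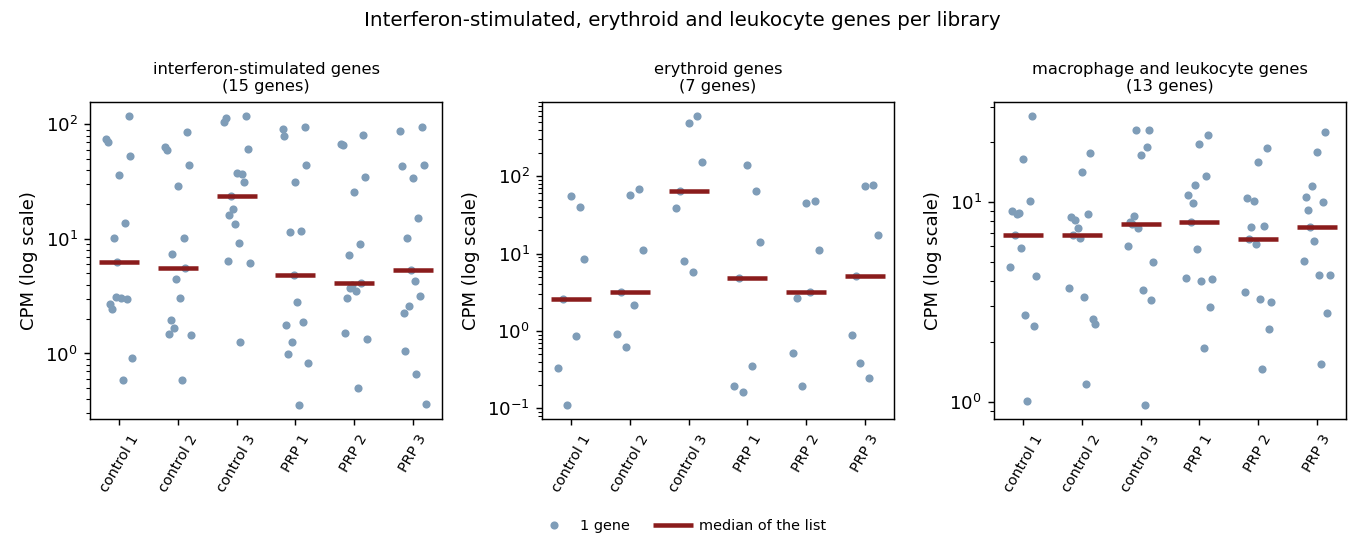
Expression in CPM on a log scale of interferon-stimulated (15 genes), erythroid (7 genes) and macrophage and leukocyte genes (13 genes) in each of the 6 libraries, with 1 point per gene and a bar at the list median. Control 3 stood above controls 1 and 2 by medians of 2.7-fold, 15.5-fold and 1.19-fold.

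The PI3K-AKT-mTOR list, the pathway named in the study's question, held 30 tested genes, of which 19 lay lower in PRP. Its median log2 fold change was -0.07, and it did not pass without the block (camera adjusted p = 0.0756) or with it (adjusted p = 0.0918); 0 of its members passed on any count. Foxo3 (Entrez 56484, chromosome 10, 42181845 to 42276695), the transcription factor that keeps primordial follicles dormant, had a log2 fold change of -0.11 (-0.26 to 0.04). For Akt1 (Entrez 11651, chromosome 12, 112653821 to 112674884) it was 0.06 (-0.10 to 0.21). The receptor gene Kit and its ligand gene Kitl had log2 fold changes of -0.10 ± 0.10 and -0.17 ± 0.13 (SE). These values are from the unpaired fit. Blocked intervals lay below 0 for Foxo3 (-0.206 to -0.019), Kit (-0.191 to -0.003) and Kitl (-0.323 to -0.028), and spanned 0 for Akt1 (-0.04 to 0.151). Foxo3, Kit and Kitl were lower in PRP in every pair, but none passed (blocked edgeR adjusted p = 0.336, 0.425 and 0.355). FOXO targets had a median of 0.02 (adjusted p = 0.977), with 0 members past the threshold without the block. With it Pdk4 fell over all genes, and adjusted over the list alone Gadd45a, Pink1 and Txnip rose and Pdk4 and Rictor fell (named after their values were seen). These values are transcript levels, and phosphorylation of the pathway's proteins was not measured here.

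Markers of the other ovarian cell types did not pass as lists over all 6 libraries. Granulosa genes had a median log2 fold change of 0.06 (adjusted p = 0.674), with Foxl2, a granulosa transcription factor, at 0.09 ± 0.09 and Amh, anti-Müllerian hormone, at 0.24 ± 0.25 (SE). Medians were -0.01 for steroidogenic and theca genes (adjusted p = 0.691), 0.11 for endothelial genes (0.197), 0.16 for pericyte and smooth muscle genes (0.297, but 0.0372 with a stricter filter on low counts) and -0.03 for macrophage and leukocyte genes (0.297). Leaving out control 3 or PRP 2 let the endothelial list (adjusted p = 0.0216 and 0.00317), the pericyte list (0.045 and 0.0426) and the leukocyte list (0.0139 and 0.0426) pass upward. Erythroid genes had a median of -2.03 (adjusted p = 0.0756), which rested on control 3: without it the list turned upward (adjusted p = 0.488), and without control 1 it fell (0.00286). Adipocyte genes had a median of -0.08 (0.96) and the 4 platelet genes that could be tested one of 0.22 (0.219).

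Signalling and stress lists did not pass either over all 6 libraries. Medians were 0.04 for SRF-MRTF cytoskeletal targets (adjusted p = 0.377), -0.03 for YAP-TEAD targets (0.977), 0.00 for ERK feedback genes (0.942), 0.00 for TGF-beta targets (0.879), 0.05 for BMP targets (0.801) and 0.02 for Notch targets (0.765). Inflammatory NF-kB targets had a median of -0.17 (0.197) and pair medians of 0.08, 0.13 and -0.54; the list turned upward without control 3 (adjusted p = 0.448) and fell without control 2 (8.05e-06) or PRP 1 (0.00809). SRF-MRTF targets rose without control 3 (adjusted p = 0.0147), and ribosome biogenesis genes fell without control 1 (0.0118). Receptors for plasma and platelet factors had a median of -0.02 (0.587). Glucocorticoid targets had a median of -0.07 (0.297), clock genes -0.06 (0.691), cholesterol synthesis genes 0.01 (0.942), heat shock genes 0.03 (0.324) and unfolded protein and amino acid stress genes 0.03 (0.801). For p53 targets the median was 0.00 (0.977), for cell cycle genes -0.05 (0.324), for ribosome biogenesis genes -0.03 (0.246) and for mitochondrially encoded genes -0.04 (0.837). Median, mean and test did not share a sign in the YAP-TEAD, ERK feedback, FOXO, macrophage and leukocyte, adipocyte, cholesterol synthesis, unfolded protein, p53 and mitochondrially encoded lists. In the unpaired fit 0 members of the lists in this and the previous paragraph passed over all genes, and adjusted over the list alone ATP6 passed, in the mitochondrially encoded list.

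With the block, single members of these lists passed adjusted over the list alone, and they too were named after their values were seen. Both inducible Hsp70 genes rose, Hspa1a by 0.61 and Hspa1b by 0.50, although they are near-identical copies. Tagln and Cnn2, actin-binding proteins of the SRF-MRTF list, rose, as did Ccn2 of the YAP-TEAD list (0.36), the Notch target Nrarp (0.40), Ddit4 of the glucocorticoid list (0.22), Manf of the unfolded protein list (0.18) and the mitochondrial genes ATP6 and COX2. Spry1, a feedback inhibitor of ERK signalling, rose by 0.35 and Spred1, another, fell by 0.18. Among TGF-beta targets Junb, Bhlhe40, Smad7 and Tgfbi rose and Skil fell by 0.30. Star, which delivers cholesterol for steroid synthesis, fell by 0.46, and Pdk4 fell within the glucocorticoid list. Of all these, Junb, Bhlhe40, ATP6 and Pdk4 also passed over all genes tested.

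**Figure D3:**
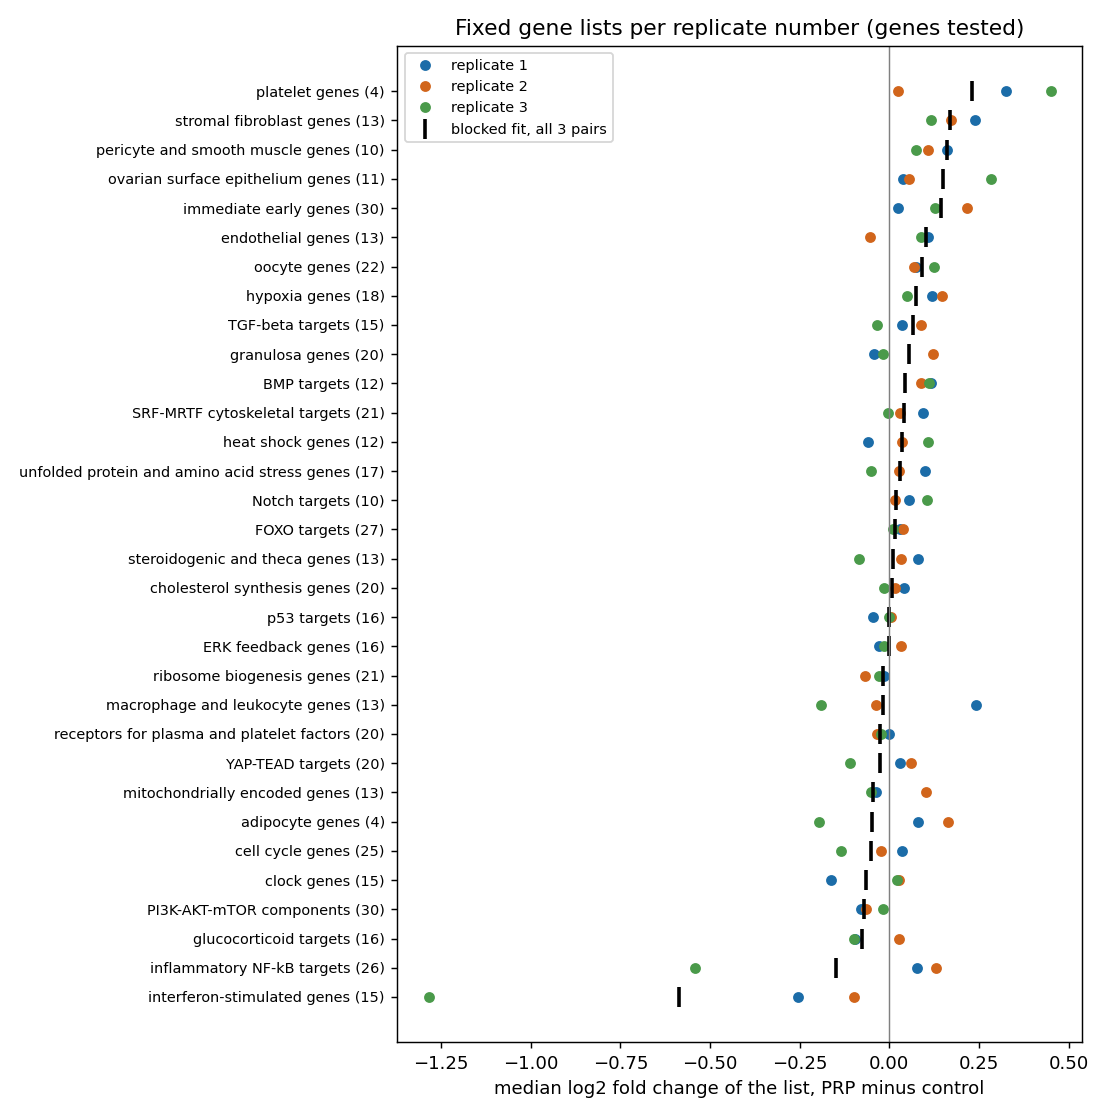
Median log2 fold change, PRP minus control, of each fixed gene list within replicate numbers 1, 2 and 3 (points) and in the blocked fit (black ticks), with the number of genes tested in parentheses; the erythroid list, with pair medians of 0.68, -0.37 and -3.63, is left out. Stromal fibroblast genes lay above 0 in all 3 pairs, and interferon-stimulated genes lay below 0 in all 3, at -1.29 in pair 3.

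The other genes that passed with the block belonged to several groups or to none of the lists. Bfsp1, a beaded filament protein of the lens, rose by 0.32 ± 0.05, Tbx2, a T-box transcription factor, by 0.38 ± 0.06, Htra3, a secreted serine protease, by 0.29 ± 0.05, Il11ra1, an interleukin 11 receptor, by 0.41 ± 0.07, Bhlhe40, a clock-linked repressor, by 0.30 ± 0.05 and Fam171a2 by 0.44 ± 0.08 (SE). Slc30a1 (Entrez 22782, chromosome 1, 191906697 to 191913248) averaged 81.6 ± 3.6 CPM in control and 62.6 ± 5.6 CPM in PRP (SD, n = 3), and Pdk4 (Entrez 27273, chromosome 6, 5483351 to 5496278) averaged 48.9 ± 8.8 and 36.9 ± 7.9 CPM. Txnrd1, thioredoxin reductase, fell by 0.25 ± 0.04, Usp9x, a deubiquitinase, by 0.23 ± 0.04, and Iigp1, an interferon-inducible GTPase, by 0.59 ± 0.09 (SE). The remaining calls are uncertain. Oip5os1 (-0.41 ± 0.07 SE) neighbours Oip5 on an unstated strand, D830031N03Rik (-0.43 ± 0.06 SE) lies within Macf1, and ATP6 (0.95 ± 0.16 SE) averaged 5.68 CPM in control against 7935 CPM for COX1 of the same mitochondrial genome and overlaps ATP8. The blocked genes were named after their values were seen.

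Of the genes with the smallest unpaired p-values in edgeR, ATP6 had an unadjusted p of 0.000684 and Slc30a1 an unadjusted p of 0.000887, and their adjusted p was 1. Speg, a striated muscle kinase, had a log2 fold change of 0.55 ± 0.14, Rtl3, a retrotransposon-derived gene, 0.51 ± 0.14, and Dpysl4 0.41 ± 0.11. Pbrm1, a chromatin remodelling subunit, had one of -0.24 ± 0.06, Rbm15, an RNA-binding protein, -0.36 ± 0.09, and Cftr, a chloride channel, -0.59 ± 0.15 (SE). None of these 6 passed with or without the block.

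In data simulated with each gene's own estimate of its dispersion and no change, the blocked fit called a median of 8 genes and up to 26. It called 21 or more in 1 of 20 draws. Genes varied independently in these draws, so the share expected when genes vary together could not show. Of the 21 genes, 20 had a GC content and length, of which 11 passed after correction for both and Junb, Zp3, Krt19, Htra3, Il11ra1, Bhlhe40, Fam171a2, Usp9x and Oip5os1 did not. In limma-voom or without robust estimation 0 of the 21 passed, and 1, 1 and 4 passed without replicate 1, 2 and 3.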

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

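The alternatives to the blocked results were chosen after the result was seen, and the others were planned. In the unpaired comparison every other test, scaling and filter tried gave 0 genes, as did leaving out each library, and the replicate block gave 21. The 6 named genes that gained a call did so with the block: ATP6, Htra3, Slc30a1, Oip5os1, Krt19 and Egr1. Against these 21, DESeq2 with the block called 88 genes (40 higher, 48 lower; 14 shared), no filter on low counts 333 (all 21 shared), and limma-voom, no robust estimation and no replicate block 0 each; without a replicate the count ran from 1 to 19. DESeq2 size factors and the stricter filter each kept all 21, and library size alone gave 28. The cause was not tested, except that fewer samples enter when a replicate is left out. The camera count of 4 lists became 0 with an estimated correlation and 0 with fry, and ran from 1 to 8 without a replicate, at 2 without control 2, 7 without control 3, 8 without PRP 2 and 1 without PRP 3. The stricter filter gave 5 lists, adding pericyte and smooth muscle genes (adjusted p = 0.0372; also 0.045 without control 3 and 0.0426 without PRP 2), and the replicate block 6 with 4 shared. These 6 became 0 with an estimated correlation and 0 with fry, 5 after GC and length correction, and ran from 2 to 8 without a replicate. The block moved no call of the other lists. Ribosome biogenesis genes fell without control 1 (adjusted p = 0.0118). Depth limits genes of few counts: 4 of 13 platelet genes could be tested.

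Reversals were among values that had not passed. ERK feedback genes turned up with fry (adjusted p = 0.993) and the block (0.975), and FOXO targets with fry (0.993), the block (0.969) and shared genes removed (0.751). The cause was not tested. Leaving out 1 library turned Fos (log2 -0.12 to 0.37, below 0 without control 2 or PRP 3) and Kit (-0.18 to 0.017, above 0 without control 2). Directions of these lists also turned without some library, with adjusted p from 0.506 to 0.912 for BMP, 0.363 to 0.951 for ERK feedback, 0.633 to 0.942 for FOXO, 0.134 to 0.902 for Notch, 0.0147 to 0.98 for SRF-MRTF, 0.244 to 0.942 for TGF-beta and 0.0814 to 0.942 for YAP-TEAD targets. Ranges were 0.28 to 0.902 for adipocyte, 0.0502 to 0.815 for cell cycle, 0.365 to 0.97 for cholesterol synthesis, 0.467 to 0.951 for clock, 0.00317 to 0.902 for endothelial, 0.00286 to 0.488 for erythroid, 0.365 to 0.969 for granulosa and 0.00169 to 0.926 for immediate early genes. They were 8.05e-06 to 0.724 for NF-kB targets, 0.0139 to 0.992 for macrophage and leukocyte, 0.648 to 0.951 for mitochondrially encoded, 0.673 to 0.95 for p53, 0.158 to 0.776 for receptor, 0.244 to 0.949 for steroidogenic and 0.0944 to 0.902 for unfolded protein genes. A low end under 0.05 is a call gained when 1 library was left out.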

Other observations

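The KEGG and GO sets, the GC and length test of the 21 genes and both tests of the interferon pattern were chosen after the result was seen; the splits and the tests on Slc30a1 and Txnrd1 were written before theirs.

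Ribosomal protein genes, of which the fixed lists held Rps6, lay slightly but evenly higher in PRP. Of 133 genes in the KEGG ribosome set, 121 had a blocked log2 fold change above 0, with a median of 0.11 and pair medians of 0.13, 0.07 and 0.12. The set rose in camera without the block (adjusted p = 1.43e-11 over 322 KEGG sets) and with it (adjusted p = 4.58e-10), but with an estimated correlation the adjusted p was 0.997 and 0.971. Its median was 0.08 after correction for GC content and length. Oxidative phosphorylation, with 101 of 128 genes above 0 and a median of 0.07, rose as well (blocked adjusted p = 0.00312; adjusted p = 0.971 with an estimated correlation). None of the 133 ribosome genes passed alone, and many have near-identical pseudogenes.

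Among 4026 GO sets, 23 passed without and 20 with the block, and 0 with an estimated correlation in either fit. Extracellular matrix genes rose in the blocked fit (228 genes, median 0.10, adjusted p = 0.00374), and genes for RNA export from the nucleus fell (17 genes, median -0.11, adjusted p = 0.031) but did not pass without the block (adjusted p = 0.0636). Genes for ATP-dependent chromatin remodelling fell without the block (31 genes, adjusted p = 0.0483) and did not pass with it (adjusted p = 0.105). With an estimated correlation the adjusted p of these 3 GO sets was 0.999 without and 0.997 with the block. The KEGG PI3K-Akt set of 306 genes had a median of 0.01 (blocked adjusted p = 0.962) and ranked 255 of 322, with 1 member past the threshold in the blocked fit over all genes.

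The first pattern is the set of 21 genes called with the block, and the lists beside them. The 4 splits that part every pair are too few for a share under 0.05; the real one gave 21 genes (1 split as large; highest other 0) and 6 lists (1 as large; highest other 4). Unpaired, the 10 splits are also too few, with 0 genes for the real split (10 splits as large, itself included; highest other 6) and 4 lists (7 as large; highest other 16, with control 1, control 2 and PRP 2 on one side, which points to the structure by replicate number). A trend of fold change with GC content (r = 0.308 across 11040 genes, which are not independent; 0.41, 0.11 and 0.10 in the pairs) is argued against as the whole cause, since the 20 genes with values kept a median 0.89 of their log2 fold change after correction. It may contribute to the 9 calls that ended, such as Junb (0.29 ± 0.05 to 0.21 ± 0.05 SE) and Usp9x (-0.23 ± 0.04 to -0.16 ± 0.04), whose changes shrank with little change in the error, and false calls by the blocked fit and a response to PRP stay open.

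The second pattern is the lower level of interferon-stimulated genes in PRP. Without control 3 the list had an adjusted p of 0.365, and medians in pairs 1 and 2 were -0.26 and -0.10, with 12 and 9 of 15 members below 0. Dependence on a single control library therefore cannot be told apart from a smaller difference in all pairs. Leukocytes in control 3 might add such transcripts, but the leukocyte list stood only 0.25 log2 above controls 1 and 2 there, against 1.43 for the interferon list. Since leukocyte genes already had a median of 6.84 CPM in controls 1 and 2, a small added share would be hidden, and this explanation and an effect of PRP both stay open.

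The third pattern is the fall of Slc30a1 and Txnrd1, a zinc exporter gene induced by metals and a target of the stress factor NRF2. GC content and length are argued against as the whole cause, because both genes kept at least 0.93 of their log2 fold change after correction. A candidate explanation is less metal-responsive transcription. Mt1 and Mt2, metallothionein genes, had blocked log2 fold changes of -0.10 ± 0.07 and -0.31 ± 0.11 (SE), each higher in 1 of 3 pairs. The 5 tested metal-responsive genes, these included, had a median of -0.01 ± 0.17 (SE over genes), which is the value of Slc39a10. Mt3 (0.70 ± 0.37 SE) and Slc30a2 (0.18 ± 0.36 SE) averaged only 1.13 and 1.17 CPM in control. So few well-counted members cannot decide, which leaves this explanation open. Another is less NRF2-dependent transcription, yet 18 other NRF2 targets had a median of -0.02 ± 0.04 (SE over genes; -0.024 before rounding, blocked camera p of 0.393 in limma), while Srxn1 (-0.28 ± 0.06), Slc7a11 (-0.28 ± 0.07) and Gclc (-0.25 ± 0.08 SE) lay about as low as Txnrd1 without passing and Ephx1 lay higher (0.52 ± 0.15), so that this stays open too. An effect of PRP on zinc or redox balance was not tested.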
